A study of Mus musculus with 6 samples.

How the data were processed

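Cerebellar genomic DNA of 6 mice of the C57BL/6 strain, all 16 weeks old, was profiled for 5-hydroxymethylcytosine (5hmC), an oxidised form of 5-methylcytosine that is abundant in neurons. The labels give 3 wildtype littermates and 3 animals titled rCGG. These model fragile X-associated tremor/ataxia syndrome (FXTAS), a disorder of carriers of an expanded CGG repeat. Per the labels' protocols, 5hmC was tagged enzymatically with a modified glucose, coupled to biotin and captured on streptavidin beads. The captured fragments were sequenced from one end for 38 cycles. Such capture measures relative enrichment over stretches about as long as the captured fragments and gives no methylation level per cytosine.

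The files used here hold the outcome of the authors' comparison of the genotypes as 2 lists of differentially hydroxymethylated regions, 1 specific to wildtype and 1 specific to rCGG. Each line gives a chromosome, a start, an end, a peak name and a score. The reads had been aligned with Bowtie 0.12.9, HOMER had also been used, and the genome build was mm9, per the submitters' processing notes. The peak names in the files are those written by the peak caller MACS; its version, its settings, the control it used and whether the 3 libraries of a genotype were pooled are not given in the sources used here. The score of each region was deposited by the authors without a header. Its lowest value was 50.00 in both lists, and its scale was not stated, so it was used only to describe, rank or filter regions. Peak numbers ran without a gap from 1 to the last line of each list. The build was taken from those notes. A total of 106 regions on 4 chromosomes lay beyond the last gene of the GRCm38 gene table, which alone does not exclude that build. All coordinates below are given as mm9 and counted from 1.

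No values per animal and no read counts were used here. Depth per library is therefore unknown, differences between animals of 1 genotype cannot be seen, and the unit of every test is the region, not the animal. The p-values describe how regions of the 2 lists are distributed. They do not test whether the lists themselves would recur in other animals. Confidence intervals are 95% exact intervals (Clopper-Pearson for shares, Poisson for densities) and cover counting error only. Neighbouring regions are not independent, which makes tests on single regions too liberal, so for chromosomes a test that keeps neighbouring regions together is given beside Fisher's exact test.

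The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The share of regions in each list was compared with an even split by an exact binomial interval. Widths were compared by permuting list labels over regions 100000 times. The wildtype-specific share on each chromosome was compared with the share elsewhere by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes, and again by moving whole 1 Mb windows between chromosomes in 10000 permutations. Density per chromosome was the number of regions divided by the length between the first and the last region. For spacing, the nearest region of either list was found for every region. The share of regions whose neighbour was of the same list was compared with 10000 permutations of list labels within chromosomes. Windows of 1 Mb with at least 3 regions were tested for imbalance by an exact binomial test against the overall share, with Benjamini-Hochberg adjustment. A chain was a run of successive rCGG-specific regions with gaps under 10 kb or 100 kb and no wildtype-specific region between them. Permutation tests are two-sided, except those of single-list windows and of chains of regions, which are one-sided.

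The tests of list size, width, chromosomal distribution and spacing, some of the alternative settings and the rule for what is named were fixed before the data were examined. With no annotation of the build, the rule named, per list, the 10 windows of 1 Mb with most regions, the 10 windows with the smallest p, the 5 best-scored and the 5 widest regions. Adjusted calls of windows, the width classes, the score thresholds, the count of regions near the other list, the single-list windows, the densities, the relation to gene density and the set of 6 high-scored loci were added after seeing the data. Planned comparisons of gene features, genes, 18 fixed gene lists and sequence content were not made, because they need an annotation or sequence of mm9, which was not used here; the gene table used here is of GRCm38. It served to count protein-coding genes per chromosome and to leave out olfactory and vomeronasal receptor genes, 1 of the fixed lists, in an alternative. Besides that, it was used only for the check of the build above and for the chromosomes of Pcp2 and Fmr1.

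On simulated labels over the 12969 real regions, the chromosome test recovered 100 of 100 chromosomes changed by 10 percentage points and called 1 of 400 with random labels. The changed chromosomes were always 1, 3, 4, 7 and 11, with 616 to 902 regions each. Other chromosomes, some with fewer regions, were not changed. Labels were drawn independently for each region, so these rates do not carry over to real neighbouring regions, which are not independent. The window test recovered 400 of 400 windows of at least 15 regions that were emptied of wildtype-specific regions. At that size recovery was close to certain in advance, and smaller emptied windows were not simulated. In the main test, windows of 8 and 7 rCGG-specific regions alone did not pass (exact binomial test, adjusted p = 0.0633 and 0.0711). The window test made no call in 20 runs of random labels drawn independently for each region. Windows emptied of rCGG-specific regions were not simulated. In the main test a window of 22 wildtype-specific and 0 rCGG-specific regions did not pass (exact binomial test, adjusted p = 0.0633), so sensitivity in that direction is lower. The permutation test of spacing passed a threshold of 0.05 in 20 of 20 runs in which 30% of labels were copied from the preceding region and in 2 of 20 runs of random labels.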

Results

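Genome-wide 5hmC was compared between the cerebella of 3 wildtype mice and 3 rCGG mice, a model of FXTAS, a late-onset neurodegenerative disorder of carriers of an expanded CGG repeat in FMR1. The comparison asks where the cerebellar 5hmC pattern differs in animals with the repeat. The deposited result comprised 12969 differentially hydroxymethylated regions on the 19 autosomes and the X chromosome. Library depth is unknown, and the regions carry the authors' score in place of an enrichment value per animal.

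Regions that the authors listed as specific to wildtype outnumbered those listed as specific to rCGG. There were 8658 wildtype-specific and 4311 rCGG-specific regions, a ratio of 2.01 to 1. The wildtype-specific share was 66.8%, with a 95% exact binomial interval of 65.9% to 67.6% that excludes 50%. Wildtype-specific regions covered 8.10 Mb and rCGG-specific regions 4.35 Mb. The share among better-scored regions was higher: 77.4% of regions with a score of at least 100 (533 against 156) and 89.4% of those with a score of at least 150 (76 against 9) were wildtype-specific. The lists were disjoint apart from 1 pair of regions on chromosome 11, a wildtype-specific region at 107073551-107074109 and an rCGG-specific region at 107073966-107074745, which shared 144 bp. Without depth per library, the effect of unequal sequencing on the balance of the lists could not be assessed, and score thresholds act on lists that were called separately.

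Wildtype-specific regions were narrower than rCGG-specific regions. Their median width was 691 bp (interquartile range 531 to 993 bp) against 853 bp (714 to 1060 bp). The difference of medians, wildtype minus rCGG, was -162 bp (permutation test, p = 1e-05, the smallest that 100000 permutations can give). The wildtype list was also the more spread out, with more regions at both ends of the range. Regions under 500 bp made up 15.9% of it against 2.57% of the rCGG list (Fisher's exact test, adjusted p = 2.87e-137), and regions over 2 kb made up 6.92% against 5.31% (Fisher's exact test, adjusted p = 0.000387). The shortest region had 294 bp in the wildtype list and 351 bp in the rCGG list. Widths are set by the peak caller, and its settings and the depth of the libraries are unknown. Whether the difference in width lies in the calling or in 5hmC was therefore not tested. The widest wildtype-specific region lay on chromosome 5 at 115021880-115030220 and had 8341 bp. It was followed by 7960 bp on chromosome 10 at 80605749-80613708 and 7731 bp on chromosome 5 at 137959508-137967238. The widest rCGG-specific regions had 5375 bp, on chromosome 15 at 87525230-87530604, and 5183 bp, on chromosome 14 at 26159148-26164330.

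The balance between the lists differed from chromosome to chromosome. Chromosome 11 had the highest wildtype-specific share, 77.5% (95% exact interval 74.6% to 80.3%; 663 of 855 regions), followed by chromosome 7 with 75.9% (666 of 878) and chromosome 4 with 74.7% (674 of 902). Chromosome 3 had the lowest, 55.8% (51.8% to 59.8%; 344 of 616), followed by chromosome 1 with 57.3% (502 of 876), chromosome 16 with 58.7% (267 of 455), chromosome 18 with 59.0% (249 of 422) and chromosome 14 with 59.7% (329 of 551). Fisher's exact test gave adjusted p-values of 2.03e-11 for chromosome 11, 1.09e-08 for chromosomes 1 and 7, and 4.11e-08 for chromosome 3. Of the 20 chromosomes, 10 passed an adjusted p of 0.05, 4 with a higher and 6 with a lower share than elsewhere. When whole 1 Mb windows were permuted, 6 of these 10 remained, chromosomes 1, 3, 4, 7, 11 and 16. Their adjusted permutation p-values were, in that order, 0.002, 0.003, 0.0072, 0.0035, 0.0033 and 0.035, larger than those of Fisher's exact test. Chromosomes 14 and 18 then had adjusted permutation p-values of 0.0543 and 0.0570, and chromosomes 8 and 19 each had 0.288. Among regions with a score of at least 75, chromosomes 3 and 16 lost their call, with shares of 72.4% and 67.7% (Fisher's exact test, adjusted p = 0.698 and 0.248, the highest over 5 alternatives), as did chromosomes 8, 18 and 19. The share over all regions at that threshold was 74.98% (2161 against 721), higher than in the main test. Chromosome 3 lay close to it. Chromosomes 8, 16 and 18 (69.2%, 67.7% and 66.3%) still lay below it and chromosome 19 (83.7%) above it. Fewer regions were tested there, so the loss of these 4 calls does not show a smaller difference.

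The wildtype list varied more in density between autosomes than the rCGG list. Wildtype-specific regions ranged from 2.30 per Mb on chromosome 3 to 5.59 per Mb on chromosome 11, a 2.43-fold range. The rCGG-specific regions ranged from 1.42 per Mb on chromosome 7 to 2.11 per Mb on chromosome 18, a 1.48-fold range. On all 19 autosomes the wildtype-specific density was the higher.

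**Figure D1:**
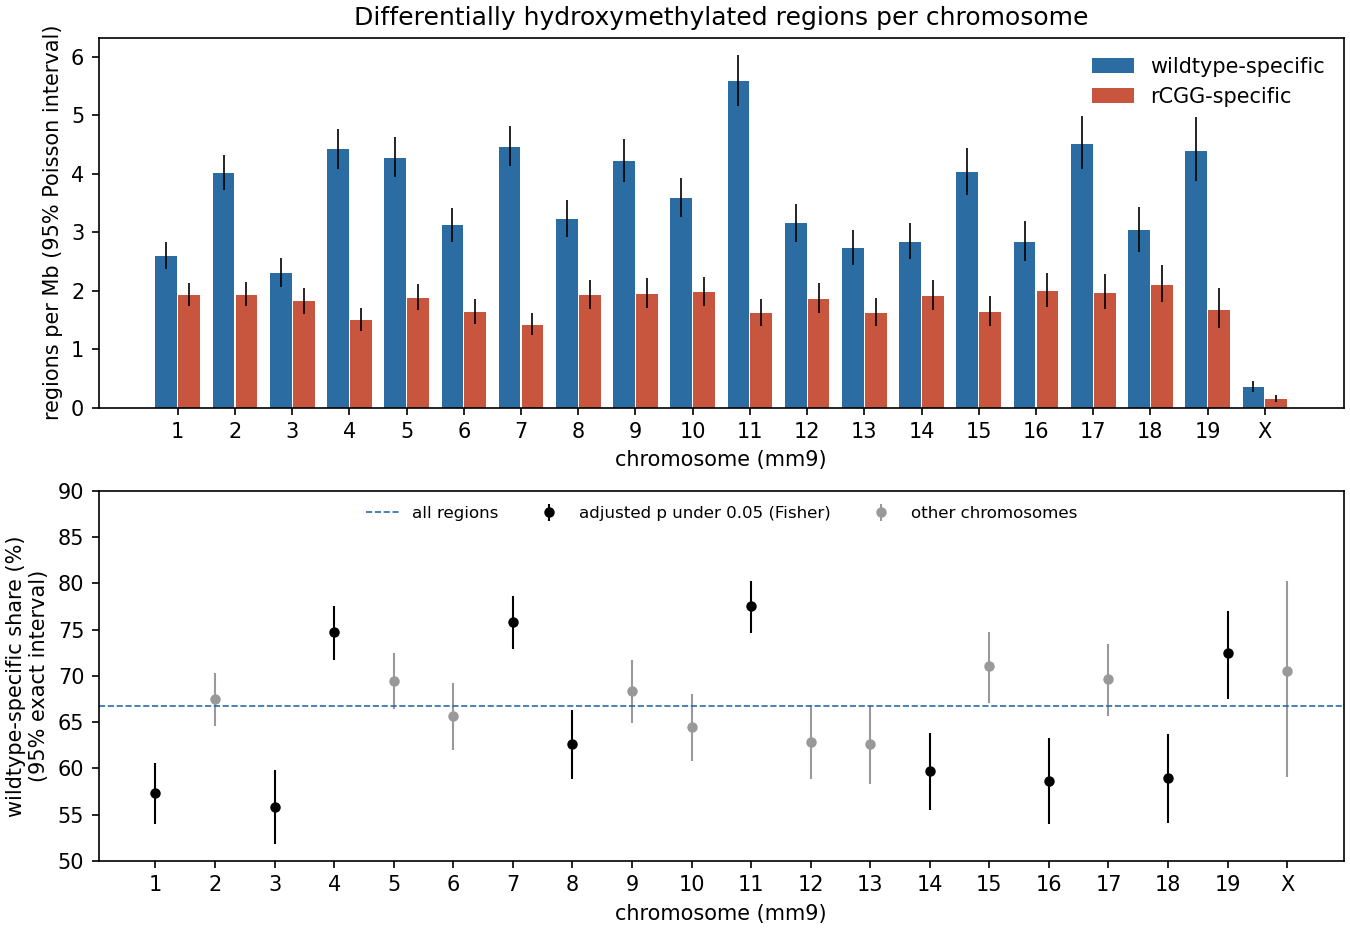
Upper panel: regions per Mb (bars, with 95% Poisson intervals) of the wildtype-specific and rCGG-specific lists on each chromosome. Lower panel: wildtype-specific share in percent (points, with 95% exact intervals; axis from 50% to 90%) against the share over all regions (dashed line, 66.8%). Wildtype-specific density peaks on chromosome 11, both densities are lowest on X, and the share runs from 55.8% on chromosome 3 to 77.5% on chromosome 11.

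The X chromosome held few regions of either list. It carried 55 wildtype-specific regions, 0.345 per Mb against 3.62 per Mb on the autosomes, a ratio of 0.0955 (95% exact interval 0.0719 to 0.124). It carried 23 rCGG-specific regions, 0.144 per Mb against 1.80 per Mb, a ratio of 0.0801 (0.0508 to 0.12). The intervals of the 2 ratios overlap, and the wildtype-specific share on X, 70.5% (59.1% to 80.3%), was not distinguished from that elsewhere (Fisher's exact test, adjusted p = 0.576). The labels give no sex for the animals. Of the 23 rCGG-specific regions on X, 6 lay within 20.9 kb, at 65948186-65969077, with no wildtype-specific region among them.

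Regions of the same list lay next to each other more often than under permuted labels. The nearest region was of the same list for 66.4% of all regions, against 56.4% ± 0.507 (SD over permutations) when labels were permuted within chromosomes (permutation test, p = 1e-04, the smallest that 10000 permutations can give). For wildtype-specific regions the share was 75.4% against 67.3%, and for rCGG-specific regions 48.2% against 34.4%. A total of 313 rCGG-specific regions (7.26%) had a wildtype-specific region within 10 kb, where labels permuted within chromosomes gave 664 ± 18.5 (permutation test, p = 0.000999, the smallest that 1000 permutations can give). This count was not repeated with labels permuted within 1 Mb windows or after merging regions of a list closer than 10 kb. It may therefore reflect imbalance over megabases or tight groups of regions of 1 list. Gaps under 10 kb within a list numbered 1058 for wildtype and 212 for rCGG. With labels permuted within 1 Mb windows, the excess of same-list neighbours over permuted labels was 4.02 percentage points. It was 0.326 points (permutation test, p = 0.471) once regions of a list closer than 10 kb were also merged, a step that removes same-list neighbours by its construction.

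Several megabase windows held regions of a single list. On chromosome 16, the window 24000001-25000000 held 10 rCGG-specific and 0 wildtype-specific regions (exact binomial test, adjusted p = 0.0249), with scores up to 103.64. On chromosome 7, the window 52000001-53000000 held 25 wildtype-specific and 0 rCGG-specific regions (exact binomial test, adjusted p = 0.0423), and its best-scored region reached 411.93. These 2 windows passed the adjusted threshold among the 1511 tested, and 281 passed an unadjusted p of 0.05, where independent labels would give 48.9. Each window was compared with the overall wildtype-specific share of 66.8%, while the share was 58.7% on chromosome 16 and 75.9% on chromosome 7. The calls therefore include the shift of the whole chromosome, and windows were not tested against the share of their own chromosome. The window test also takes neighbouring regions as independent. Of the 10 regions in the chromosome 16 window, 6 lay in a chain with gaps under 100 kb, at 24701762-24940620. Across the 1511 windows the Pearson dispersion, the observed over the binomial variance of the counts, was 2.16. The adjusted p-values of both windows are therefore too liberal, and by how much was not tested. The chromosome 7 window did not pass after regions closer than 10 kb were merged. Shifting the windows by 500 kb gave 7 windows past the threshold and windows of 2 Mb gave 59.

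Besides that chromosome 7 window, the windows richest in wildtype-specific regions were on chromosome 10 at 80000001-81000000, with 27 against 1, and on chromosome 19 at 42000001-43000000, with 25 against 3. Chromosome 15 at 84000001-85000000 followed with 23 against 3. Chromosome 7 also held 22 against 0 in 134000001-135000000 and 21 against 0 in 29000001-30000000, and chromosome 15 held 21 against 0 in 79000001-80000000. None of these passed the adjusted threshold (exact binomial test, adjusted p from 0.0633 to 0.191). The other windows richest in rCGG-specific regions were less one-sided than that on chromosome 16. Chromosome 14 at 22000001-23000000 held 11 rCGG-specific and 6 wildtype-specific regions, chromosome 3 at 55000001-56000000 held 10 and 4, and chromosome 15 at 30000001-31000000 held 10 and 4. Smaller windows with rCGG-specific regions alone included chromosome 6 at 50000001-51000000 with 8 and chromosome 8 at 42000001-43000000 with 7 (exact binomial test, adjusted p = 0.0633 and 0.0711). In all, 63 windows of at least 10 regions were purely wildtype-specific, where permuted labels gave a mean of 7.03 and at most 15. Windows of at least 3 regions that were purely rCGG-specific numbered 52, against a mean of 11.3 and at most 22 (permutation test, p = 0.000999 for both, the smallest that 1000 permutations can give). At that same minimum of 3 regions, 169 windows were purely wildtype-specific, against a mean of 137 and at most 170 (permutation test, p = 0.002).

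A few loci had scores far above the rest of their list. The best-scored rCGG-specific region was a single 3096 bp region on chromosome 8 at 3623305-3626400 with a score of 1868.47, where the list's median was 59.35. The scale of the score was not stated, so differences in score give an order and no size. The nearest region, a wildtype-specific one, lay 16.3 kb away. The next rCGG-specific score was 235.59, at the X chromosome locus, for the region 65948186-65948956. The remaining 5 regions of that locus had scores down to 61.99, and the 6 regions had widths of 381 to 771 bp. Chromosome 1 at 122765059-122766092 followed with 196.28, and chromosome 2 with 175.86 at 146327136-146328658 and 164.04 at 5733319-5734162.

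In the wildtype list, whose median score was 62.38, the 2 best-scored regions and the fifth lay within 5.38 kb on chromosome 2 at 98502246-98507625, with scores from 570.46 to 1545.97. A single region on chromosome 9 at 35112387-35113303 had 686.89. At the start of the chromosome 9 assembly, 16 wildtype-specific regions lay within 38.5 kb, at 2999879-3038406, with scores up to 626.83 and a median of 264. On X, the last wildtype-specific region, at 166431754-166432690, had 344.24. Leaving out 6 such loci, chosen after their scores were seen and by no fixed rule, so that the chromosome 7 region of score 411.93 was kept, changed the overall wildtype-specific share from 66.8% to 66.7%. It ended the call for chromosome 8 (Fisher's exact test, adjusted p = 0.0518; 0.0518 to 0.288 over 5 alternatives).

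**Figure D2:**
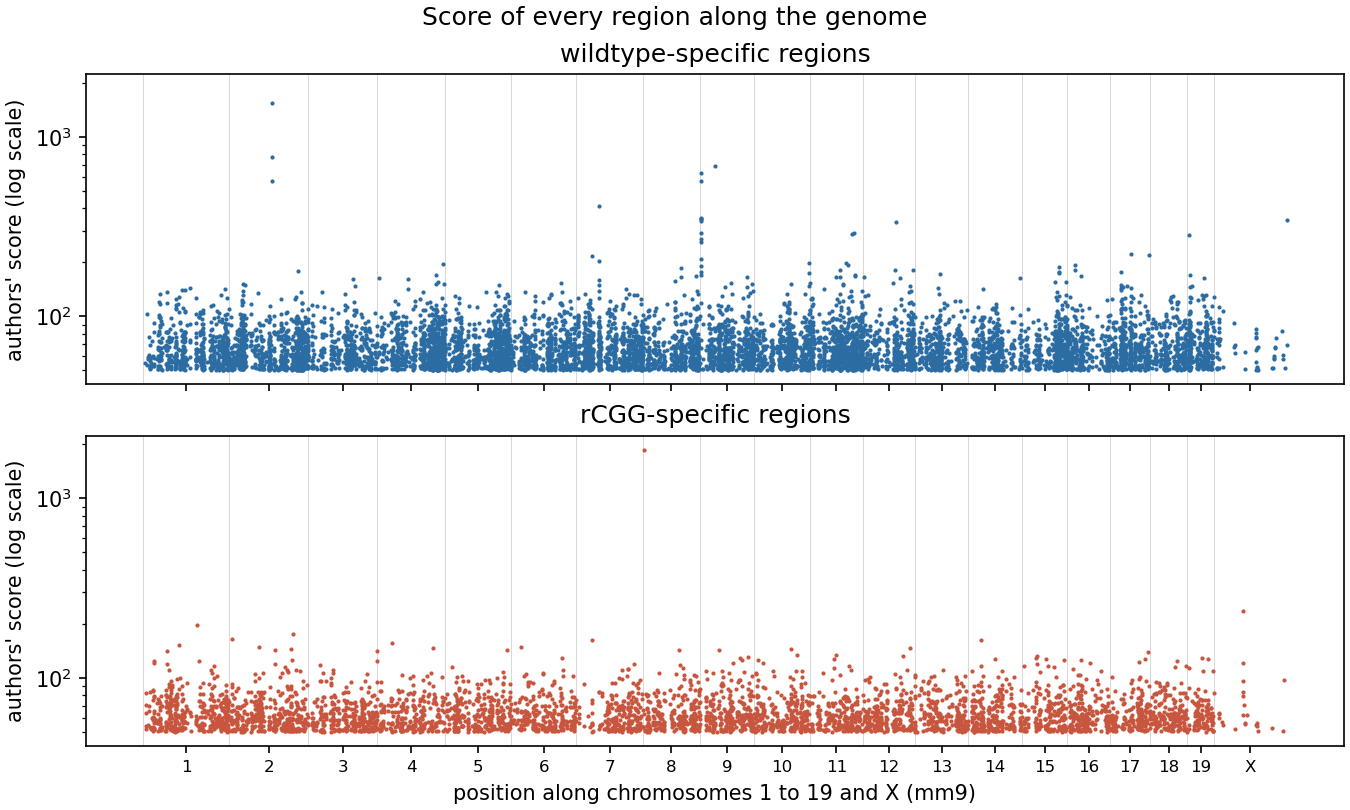
Authors' score (log axis) of every wildtype-specific region (upper panel) and rCGG-specific region (lower panel) against its position along chromosomes 1 to 19 and X of mm9. Single points far above the band are the chromosome 8 region (1868.47) in the rCGG list and the loci on chromosomes 2 and 9 (up to 1545.97 and 686.89) in the wildtype list.

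**Figure D3:**
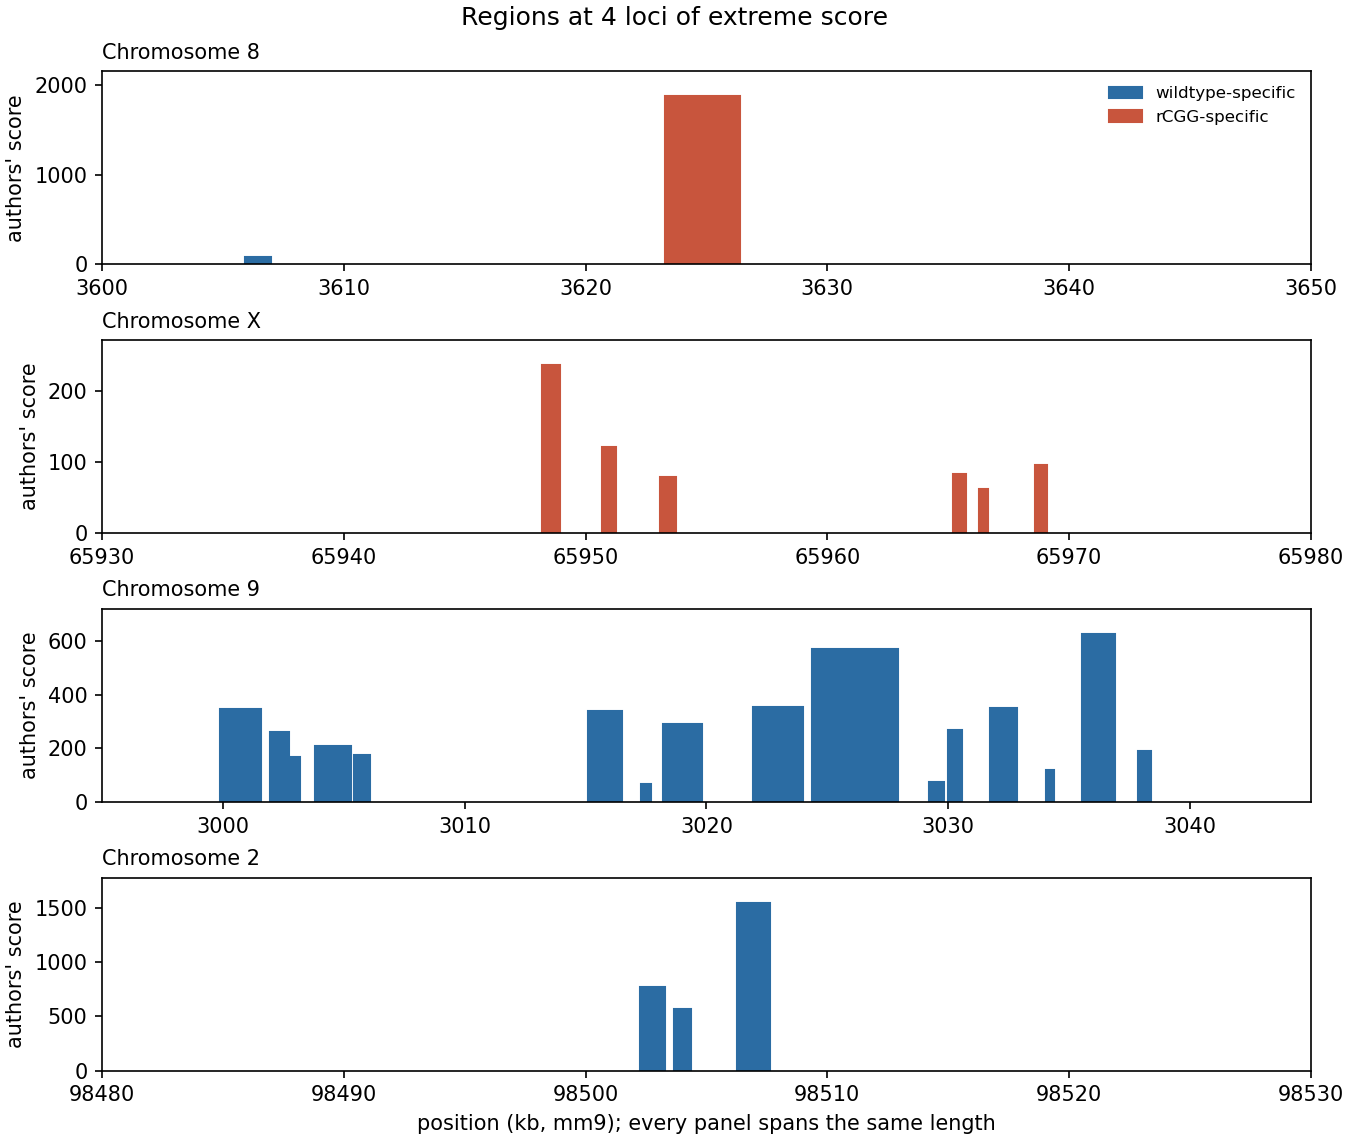
Regions at 4 loci of extreme score: each box spans a region's start and end in kb on mm9, its height is the authors' score on an axis from 0, and its colour is its list. The loci on chromosomes 8 and X hold 1 and 6 rCGG-specific regions, with a wildtype-specific region 16.3 kb from the former, and those on chromosomes 9 and 2 hold 16 and 3 wildtype-specific regions.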

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

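Score thresholds, permutation within 1 Mb windows, merging combined with permutation within 1 Mb or 10 Mb windows, all settings for imbalanced windows, the omission of 6 high-scored loci and all settings for the relation to gene density were chosen after seeing the data. The wildtype-specific share stayed above 50% in 10 of 10 alternatives, from 65.0% after merging regions of a list closer than 10 kb to 89.4% at a score of at least 150. Counted in base pairs it was 65.1%. That value, the share after merging and those at all 4 score thresholds lay outside the interval of the main value. Keeping the better-scored regions of each list down to its median score, 1 of the 10, fixes the share by its construction. The width difference stayed negative in 3 alternatives. It was -188 bp at a score of at least 75, and unchanged at -162 bp without the 6 high-scored loci and after merging overlapping or touching regions. That merging also left the share at its main value, because the only overlapping pair was of different lists, so it adds no support to either result. The number of chromosomes past the threshold was 10 in the main test, 6 with permutation of whole 1 Mb windows and 5 at a score of at least 75, where fewer regions were tested. Chromosomes 1, 4, 7 and 11 kept their call in 5 of 5 alternatives, while chromosome 8 lost it in 5, chromosome 19 in 4, chromosome 18 in 2, and chromosomes 3, 14 and 16 in 1 each. On X, which was not called, the share fell below that elsewhere at a score of at least 75 (71.4%; the cause was not tested). The excess of same-list neighbours was 9.98 points in the main test and 11.9 with neighbours within 100 kb, the only higher value. It fell to 5.16 after merging and to 2.56 with merging and permutation within 10 Mb windows. The excess was lost, at 0.326 points, when merging and permutation within 1 Mb windows were combined (permutation p = 0.471, against 1e-04, the smallest possible, in the other 7 alternatives). The gene density relation kept r between 0.749 with X and 0.845, with 0.837 without olfactory and vomeronasal receptor genes. The 2 imbalanced windows became 1 after merging, 7 after a shift by 500 kb and 59 with windows of 2 Mb, which hold more regions each. No paired analysis was possible because the lists hold no values per animal, and for the same reason no animal could be left out. Alternatives for gene features, genes, gene lists and sequence content were not run, since no mm9 annotation or sequence was used here. Unknown depth limits every comparison of list sizes.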

Other observations

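All tests in this part were chosen after the results were seen, and 3 relations to gene density were computed. Wildtype-specific regions followed gene density across the autosomes. The 5 most gene-dense autosomes (2, 7, 11, 17 and 19; 12.1 protein-coding genes per Mb) held 4.55 wildtype-specific regions per Mb, and the 5 least gene-dense (1, 3, 12, 13 and 18; 6.38 genes per Mb) held 2.70, a ratio of 1.68. The rCGG-specific regions had 1.72 and 1.86 per Mb, a ratio of 0.925. Across 19 autosomes, the wildtype-specific density correlated with genes per Mb at r = 0.854 and rho = 0.863 (permutation test, adjusted p = 3e-05 for both, the smallest that 100000 permutations over 3 relations can give here). The wildtype-specific share did so at r = 0.822 and rho = 0.825 (permutation test, adjusted p = 6e-05 and 0.000135), and at r = 0.720 without chromosomes 7 and 11, the farthest from the median. For rCGG-specific density r was -0.432 and rho -0.316 (permutation test, adjusted p = 0.0646 and 0.190), and r was -0.105 without the same chromosomes. Genes were counted per chromosome in a GRCm38 table, so positions within chromosomes were not compared.

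The relation between the wildtype-specific share and gene density remained at r = 0.813 (permutation p = 3e-05) after merging regions closer than 10 kb. That argues against groups of regions with gaps under 10 kb as its source. Groups with wider gaps, such as the one-sided megabase windows, were left in place, so their part was not tested. The relation was r = 0.845 (permutation p = 2e-05) at a score of at least 75, which argues against regions close to the calling threshold. Gene-dense chromosomes are also GC-rich, so a GC or fragment length bias between the libraries of the genotypes may give the same picture. Such a bias could push rCGG-specific regions onto gene-poor chromosomes, and the r of -0.432 there does not decide it. A hypothesis on the biological side, not tested here, is a lower 5hmC level over gene-rich sequence in rCGG cerebella, and without an mm9 sequence, input libraries or depth it and the bias cannot be told apart.

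The rCGG-specific loci on chromosomes 8 (1 region of 3096 bp, score 1868.47) and X (6 regions of 381 to 771 bp within 20.9 kb, 16.6 Mb from the preceding and 2.43 Mb from the following region) were singled out after their scores were seen. With gaps under 100 kb, the observed lists held 6 chains of rCGG-specific regions at least as long as that on X, and random labels gave 1 as long somewhere in the genome at a permutation p of 0.839; with gaps under 10 kb the locus counted as 2 chains of at most 3 regions (permutation p = 0.9999), while the 2 Mb window on X from 64000001 to 66000000 held these 6 regions and 0 wildtype-specific ones (exact binomial test, adjusted p = 0.0286, 1 of 59 windows past the threshold). The 10 kb distance splits the locus, while the 100 kb distance holds it as 1 chain of 6 regions. In the main windows of 1 Mb, 6 rCGG-specific and 0 wildtype-specific regions gave an adjusted p of 0.0986 (exact binomial test), which did not pass. The window test thus passed for this locus only with the larger windows, chosen after seeing the data, and it takes the 6 neighbouring regions as independent. Whether chance placed the labels stays open. The scores were not part of these tests. A candidate explanation, written as a hypothesis, is extra copies of these sequences in the rCGG animals (transgene); 0 wildtype-specific regions lay inside the loci, which their choice nearly fixed and which decides nothing, and no input depth was used here, so extra copies and a local gain of 5hmC cannot be told apart. From general knowledge and not from these data, models of FXTAS have been built with the Purkinje cell gene Pcp2 and with Fmr1, which the GRCm38 gene table places on chromosomes 8 and X; whether the regions overlap them was not tested.

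X chromosome regions were scarce in both lists. Wildtype-specific density on X was 0.128 of that on the 5 least gene-dense autosomes although X had 6.07 genes per Mb against their 6.38, and its upper bound of 0.450 per Mb lay under the lower bound of every autosome, which argues against low gene density as the whole explanation. A single X copy lowering depth may contribute: only 6.16% of autosomal wildtype-specific regions had a score of at least 100, which is 2 times the lowest score. How the score scales with depth is unknown and the labels give no sex, so this stays open, as does a lower 5hmC level on X in both genotypes.

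The wildtype-specific loci of extreme score on chromosome 2 (3 regions within 5.38 kb) and at the start of the chromosome 9 assembly (16 regions within 38.5 kb) were tight groups. No rCGG-specific region lay among them, which their choice after the scores were seen nearly fixed and which decides nothing. No repeat annotation, mm9 sequence or input depth was used here, so whether these scores reflect 5hmC or the sequence of the loci was not tested.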
